A study of Homo sapiens with 8 samples.

How the data were processed

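Gene expression was measured on 8 Affymetrix GeneChip arrays of the human 133A design, 1 per sample. The RNA came from MDA-MB-435 clones that carry integrin beta4 or an empty vector. Per the labels, cells grew in DMEM with 10% FCS and were harvested at 70% confluence, RNA was taken with an RNAqueous kit, and biotin-labelled cRNA was made from 8.4 ug of total RNA. The authors processed the arrays with GCOS, the Affymetrix operating software, in a version not given, and the deposited values are a linear signal intensity per probe set, scaled by the authors to the same 2% trimmed mean (499.9) on each array. The table holds 22283 probe sets, of which 68 are controls, and no detection calls. Of the probe sets, 19071 carry 1 gene symbol, 1043 several and 2169 none in the platform table; 19059 symbols were matched to the reference annotation by gene identifier and 0 had to be updated.

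Samples were grouped by the transfection their titles give (4 beta4, 4 mock), with the clone and the name suffix (none or G643) as further columns. Replicate numbers were assigned here in the order of the samples. The signal was taken as log2 of the value plus 16 with no further scaling, control probe sets were left out, and 13329 of 22215 probe sets (60%) whose mean signal over the 8 arrays lay above the 40th percentile (117) were tested; they cover 7963 genes. Beta4 was compared with mock in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with group and suffix as terms and the clone as a random block (duplicateCorrelation, consensus correlation 0.097), followed by empirical Bayes moderation (5 residual and 4.33 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05; tests were 2-sided. The 2 beta4 clones, the 2 mock clones and the suffix were compared in a fit with 1 coefficient per clone plus the suffix. A fit with a term for the difference between the suffix sets tested whether the group difference depended on the set. Controls and array summaries were compared by exact permutation tests that exchanged single arrays and ignored the clones.

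Gene groups were 27 lists, which cover integrins, matrix, cytoskeleton, signalling, lineage markers of other cell types, immune, stress, metabolic and cell cycle genes; 890 of their 977 symbols are on the array. Each gene was represented by its brightest tested probe set. The 26 lists with at least 5 tested genes were tested with limma's camera on the moderated statistics (cameraPR, preset correlation 0.01, Benjamini-Hochberg over the lists), and again with a correlation estimated per list. An estimate below the preset makes the second test more lenient than the first. The other settings below used the preset correlation for the lists. Each list's calls are also given adjusted over the list alone. Symbols older than the reference were counted only where they matched. The result of 1 list is not reported here.

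Genes named in the text follow a rule: ITGB4, ITGA6, S100A4 and ENPP2 always; the 12 largest rises and 12 largest falls among called probe sets with 1 symbol whose groups do not overlap; per list up to 4 called members with the smallest adjusted p, or 2 members with the smallest p where none is called; and for the clone and suffix comparisons the 5 largest differences each way. Further called members of a list, such as CIITA, HLA-E, HLA-DPA1, EZR, MYLK, NFKB2 and further probe sets of named genes were named after their values were seen. The comparisons, the gene lists, the rule and the first set of other settings below were fixed before the data were examined.

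These settings were offsets of 1 and 64, quantile and median scaling, no filter and a filter at the 60th percentile, an intensity trend, a required log2 difference of at least 1, no clone block, clone means, no suffix term, each suffix set alone, each array and each clone left out in turn, and for the lists the mean statistic over a gene's probe sets. Chosen after seeing the data were a fit without suffix and block together, a fit after the median of neighbouring genes was subtracted, the lists within each suffix set, and the order of genes along chromosomes. That order was taken from the reference annotation (GRCh38.p14); each gene's neighbours were the 20 tested genes on each side, compared with shuffled gene orders (1000 for correlations, 50 for the neighbour medians).

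The fits were tested on simulated data with 13329 probe sets and the same layout, in 5 simulations with 100 changed probe sets per size. The beta4 comparison recovered 63.4% of probe sets changed by 1 and 90.4% of those changed by 2 on the log2 scale, with 8.2% wrong calls, and called 0 when nothing was changed. The comparison of 3A7 with 5B3 recovered 16.4% and 69.6%, and the suffix comparison 81.4% and 97.8%. A simulated list of 25 genes shifted by 0.5 was called in 5 of 5 simulations. Its genes were simulated independently of each other, while the antigen presentation list had an estimated correlation of 0.373. The simulation thus does not show how the list test performs on lists of correlated genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genome positions are not given because the platform's build is not given in the sources used here.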

Results

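Gene expression was measured in MDA-MB-435, a human cancer cell line that the labels call breast carcinoma and that is known to share its origin with a melanoma line. The cells had been stably transfected with the integrin beta4 subunit, which pairs with the alpha6 subunit into a laminin receptor, or with empty vector. The beta4 group holds 4 arrays from the clones 3A7 and 5B3, and the mock group holds 4 arrays from the clones 6D2 and 6D7. Each clone has 1 array under its plain name and 1 under its name with the suffix G643, whose meaning is not given in the sources used here. Replicates 1 to 4 of beta4 are 3A7, 5B3, 3A7 with the suffix and 5B3 with the suffix, and those of mock are 6D2, 6D7, 6D2 with the suffix and 6D7 with the suffix. Each array gives a signal in linear units for 22283 probe sets, with a 2% trimmed mean of 499.9 on all 8 arrays and a median between 169.9 and 191.7. The number of arrays limits the precision. Nothing in the labels shows that the 2 arrays of a clone come from separate cultures, so the p-values may measure technical spread and the spread between clones only.

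The comparison of beta4 with mock asks which genes differ in cells that carry the beta4 subunit, with emphasis, by the study's title, on motility, invasion and metastasis. S100A4, a calcium-binding protein linked to cell motility, and ENPP2, the secreted enzyme autotaxin that makes lysophosphatidic acid, were both far higher in beta4. S100A4 had a signal of 9974 ± 800.3 in beta4 (SD, n = 4) and 1717 ± 433 in mock, a log2 difference of 2.56 (SE 0.172, limma adjusted p = 0.000106). ENPP2 had 2744 ± 349 against 147 ± 35.2 on its brighter probe set (log2 difference 4.10, SE 0.193, limma adjusted p = 3.73e-05). It had 1330.3 ± 234 against 166 ± 27.3 on the other (log2 difference 2.88, SE 0.177, limma adjusted p = 6.22e-05). These 3 probe sets were higher in 4 of 4 beta4 arrays than in every mock array. Both genes were named in advance because the published study of these cells reports them, so their direction is not independent evidence.

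For the transfected gene itself, all 4 probe sets of ITGB4 had a mean over the 8 arrays under the signal filter of 117. The ITGB4 probe set with the largest log2 difference had 127 ± 58.0 in beta4 and 50 ± 15 in mock. All 4 beta4 arrays lay above all 4 mock arrays (log2 difference 1.07 in a fit without the filter, limma adjusted p = 0.163). The other 3 gave 146 ± 112 against 73.2 ± 36.3, 86.8 ± 17.4 against 75.9 ± 27.4 and 9.6 ± 2.2 against 28.3 ± 35.8. In the probe set with a mean of 146, the 3A7 arrays had 152 and 299, the 5B3 arrays 37.3 and 96.3 and the mock arrays 45.7 to 122. The sources used here do not say which part of the transcript was transfected, so whether these probe sets read the introduced copy is not known. ITGA6, the partner subunit, gave 2305 ± 716 in beta4 and 1925 ± 265 in mock on its brighter probe set (log2 difference 0.21, SE 0.236, limma adjusted p = 0.656). It gave 1915 ± 705 against 1595 ± 769 on the other (0.30, SE 0.264, limma adjusted p = 0.571). These ITGA6 differences are within the spread between replicates. On the brighter probe set the difference was 0.73 among the arrays without the suffix and -0.30 among those with it.

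Log2 differences are on the scale of the signal plus 16, which understates the change of genes with a low signal in either group. Among the 24 genes with the largest differences, 16 had a group mean under the filter signal of 117, and without detection calls it is not known whether those signals lie above background. Their sizes thus depend on the offset. The largest rise on this scale was in SFRP1, a secreted antagonist of Wnt ligands, with 2101 ± 566 in beta4 and 45.0 ± 48.6 in mock (log2 difference 5.41, SE 0.391, limma adjusted p = 0.000165; 6.17 with an offset of 1 and 4.37 with 64). CHRDL1, a secreted antagonist of bone morphogenetic proteins, rose from 52.5 ± 26.4 in mock to 2293 ± 568 in beta4 (5.12, SE 0.264, limma adjusted p = 3.73e-05). MARCKS, an actin-binding substrate of protein kinase C, rose on each of its 4 tested probe sets, by 4.06, 3.92, 3.19 and 2.04 on the log2 scale. The other genes of the 12 largest rises, after ENPP2, were COL9A3 (3.92), a chain of collagen IX, the homeobox factor NKX2-2 (3.68) and the small heat shock protein CRYAB (3.63). They further include the actin-capping protein CAPG (3.33), PDLIM4 (3.24), DNAJC12 (3.05), the heparan sulfate sulfotransferase HS3ST3A1 (3.04) and TYRP1 (3.03), an enzyme of melanin synthesis. The largest fall was in SERPINA3, a secreted protease inhibitor, from 1123 ± 897 in mock to 44.6 ± 16.4 in beta4 (-4.00, SE 0.435, limma adjusted p = 0.00165). MT1E, a metallothionein, fell from 6288 ± 690.2 to 686 ± 166 (-3.19, SE 0.189, limma adjusted p = 5.99e-05). The other 10 of the 12 largest falls begin with the nicotinamide methyltransferase NNMT (-3.50), TMPRSS15 (-3.17), AUTS2 (-3.07), and the glutamine synthetase GLUL (-3.05). With them fell the glucose transporter SLC2A3 (-2.85), the cytokine LIF (-2.78), the mitochondrial carrier UCP2 (-2.65), CDC42EP1 (-2.61), the formin FHOD3 (-2.59) and the transmembrane collagen COL13A1 (-2.44). On clone means, 20 of these 24 genes stayed called, and CRYAB (limma adjusted p = 0.099), TYRP1 (0.164), CDC42EP1 (0.110) and COL13A1 (0.134) did not. Of 13 further tested probe sets for 10 of the 24 genes, 13 went the same way and 11 were called. The brighter TMPRSS15 probe set differed by -0.38 (limma adjusted p = 0.332).

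**Figure D1:**
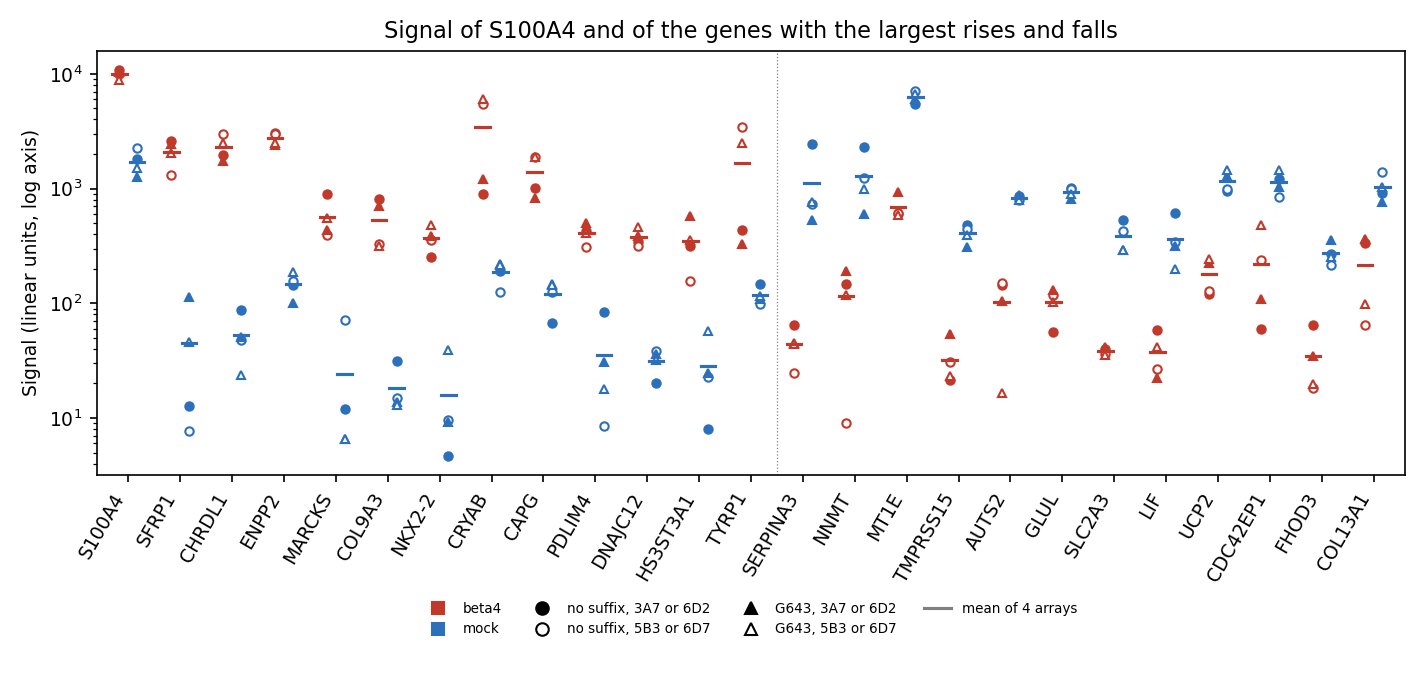
Signal in linear units (log axis) on each of the 8 arrays for S100A4 and for the 12 genes with the largest rises and the 12 with the largest falls in beta4. Circles are arrays without the suffix, triangles those with G643, filled symbols the clones 3A7 and 6D2, open symbols 5B3 and 6D7, and lines the mean of 4 arrays. In each gene the 4 beta4 values lie apart from the 4 mock values.

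Of 13329 probe sets tested, 554 were called between beta4 and mock, 300 higher in beta4 (235 genes) and 254 lower (200 genes), with 2771 at an unadjusted p under 0.05. The 4 beta4 values did not overlap the 4 mock values in 12.3% of all tested probe sets. Chance would give 2.86% if single arrays could be exchanged. The arrays come in clones, and differences between clones can raise that share, so the excess alone does not show an effect of the group. The groups did not overlap in 502 of the 554 called probe sets (90.6%), which were picked for their difference. The difference was 2-fold or more in 291. Among 195 called genes with several tested probe sets, 159 had at least 1 that was not called and 16 had probe sets of opposite sign. The arrays without the suffix alone (2 against 2) gave 91 calls and those with it 43. Over all tested probe sets the differences within the 2 sets correlated with r = 0.625. A fit of the difference between the sets called 0 probe sets, with 545 at an unadjusted p under 0.05 against 666 by chance. The count fell to 169 without mock replicate 1, 277 without mock replicate 2, 185 without mock replicate 3 and 257 without mock replicate 4. It fell to 96 without clone 6D2 and 98 without clone 6D7 and rose to 1314 without clone 3A7 and 979 without clone 5B3. It was 125 on the mean of each clone's 2 arrays, 200 with no signal filter and 972 with an intensity trend in the variance.

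Genes of antigen presentation were lower in beta4 as a group. Of 22 measured members 8 fell, 0 rose and 14 did not pass the test, and 16 fell and 0 rose when adjusted over the list alone; 21 of the 22 lay below 0. The class II gene HLA-DQA1 fell from 1047 ± 229 in mock to 265 ± 46.4 in beta4 (log2 difference -1.91) and HLA-DPB1 from 5477 ± 727 to 1998 ± 862 (-1.53). The class I genes HLA-B, from 6938 ± 1188 to 2690 ± 614 (-1.37), and HLA-C, from 8010 ± 923 to 3423 ± 797 (-1.24), fell as well. CIITA, the transactivator of class II genes, fell by 1.01 on the log2 scale, HLA-DPA1 by 0.90, HLA-E by 0.88 and PSMB9, a subunit of the immunoproteasome, by 0.69. The PSMB9 call was lost in 16 of 26 other settings. B2M, the light chain of class I molecules, gave 9790 ± 1420 against 11397 ± 629 (-0.23, limma adjusted p = 0.467). The median over the list was -0.84 (camera adjusted p = 7.02e-13, and adjusted p = 0.0246 with an estimated correlation). Probe sets of different HLA genes can share sequence, so these members are not independent measurements.

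The interferon response list was lower in beta4 too, with 4 of 34 members that fell, 0 that rose and 30 that did not pass; adjusted over the list alone, 12 fell and 1 rose. ISG15, a ubiquitin-like protein induced by interferon, fell from 1621 ± 486 to 702 ± 113 (log2 difference -1.16), XAF1 from 269 ± 38.9 to 103 ± 46.2 (-1.34) and ISG20 from 381 ± 82.8 to 128 ± 66.5 (-1.55). The remaining one, PSMB9, is also on the antigen presentation list. The list's median was -0.23 (camera adjusted p = 0.000328, and adjusted p = 0.0335 with an estimated correlation). Both the antigen presentation and the interferon list kept their call in 20 of 20 other settings, including the arrays without the suffix alone and those with it alone. The interferon median was -0.36 without beta4 replicate 1, -0.36 without clone 5B3 and -0.39 among the arrays without the suffix, and the antigen presentation median was -0.55 without clone 5B3. Of 4 tested leukocyte markers, which another cell type would bring, 0 passed the test, also when adjusted over the list alone. FCER1G gave 210.1 ± 25.1 in beta4 and 169 ± 43.2 in mock and LAPTM5 221 ± 76.7 and 249 ± 56.1. With the filter that list was too short for a group test. With no filter its 17 members on the array had a median of -0.09 (camera adjusted p = 0.87, and between 0.578 and 0.992 over the settings that left at least 5 members to test).

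**Figure D2:**
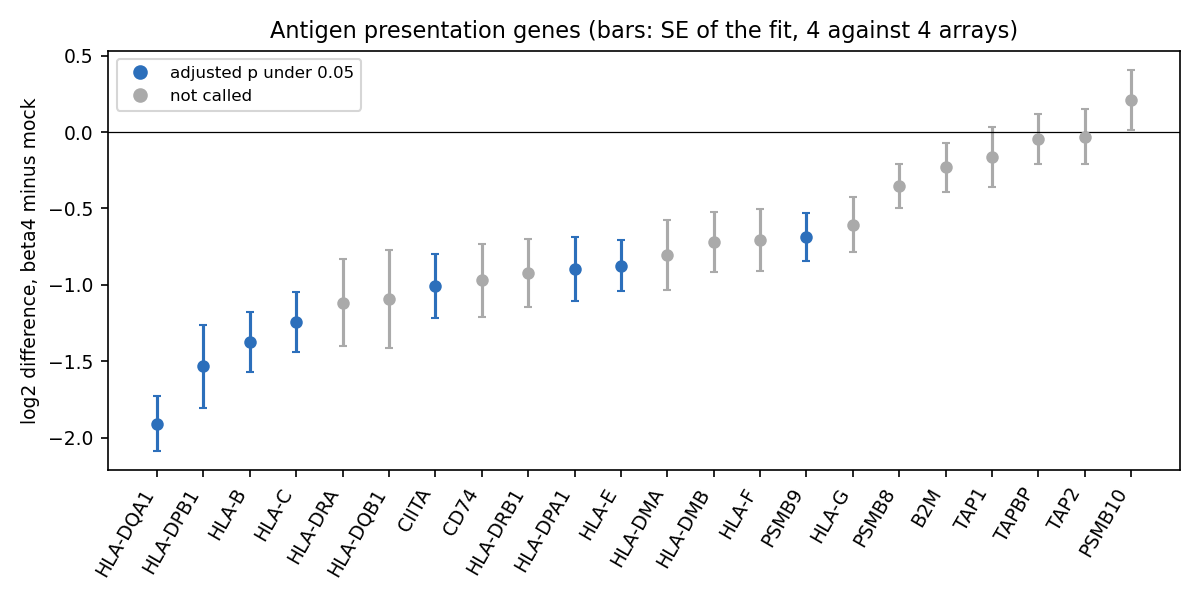
Log2 difference of beta4 minus mock for the 22 measured antigen presentation genes, with the SE of the fit over 4 against 4 arrays as bars. Filled blue points mark the 8 genes that passed the test and grey points the others; 21 of the 22 lie below 0, from -1.91 for HLA-DQA1 to 0.21 for PSMB10.

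Immediate early genes, which growth factor signals induce within minutes, gave 2 that fell, 1 that rose and 23 that did not pass of 26. The counts were 7 that fell and 1 that rose when adjusted over the list alone. FOSL1, a subunit of the AP-1 transcription factor, fell from 9791 ± 1573 in mock to 2786 ± 1212 in beta4 (log2 difference -1.91). EGR1 fell from 431 ± 189 to 146 ± 38.2 (-1.40), and the phosphatase DUSP4 rose from 1569 ± 233 to 3255 ± 668 (1.04). A second probe set of each of the latter genes differed by -0.30 (EGR1, limma adjusted p = 0.656) and 0.06 (DUSP4, limma adjusted p = 0.915). The list's median was -0.53 (camera adjusted p = 0.0018, but adjusted p = 0.365 with an estimated correlation). It kept its call in 17 of 20 other settings, and was also not called among the arrays with the suffix (adjusted p = 0.131) or without clone 6D2 (0.0512). The median was -0.335 without beta4 replicate 2 (adjusted p = 0.0154), -0.33 without mock replicate 1 (0.0354), -0.275 without clone 5B3 (0.0242) and -0.305 without clone 6D2. It was -0.925 among the arrays without the suffix and -0.25 among those with it.

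Cytokines, chemokines and angiogenic factors gave 4 of 29 that fell, 1 that rose and 24 that did not pass, with the same counts of 4 and 1 when adjusted over the list alone. LIF fell from 366 ± 175 to 37.4 ± 16.2, IL24 from 189 ± 116 to 46.9 ± 41.8 (log2 difference -1.80). TNFAIP3, an inhibitor of NF-kappaB signalling, fell from 798 ± 167 to 377 ± 83.6 (-1.05) and NFKB2 by 0.70 on the log2 scale. The guidance factor SEMA3A rose from 192 ± 31.0 to 372 ± 74.6 (0.90). The list was called lower (camera adjusted p = 0.0205, but adjusted p = 0.161 with an estimated correlation). It kept its call in 12 of 20 other settings. The call was lost among the arrays with the suffix (adjusted p = 0.556) and without clone 3A7 (0.144), 6D2 (0.329) or 6D7 (0.0598). It was also lost without beta4 replicate 1 (0.0831), mock replicate 1 (0.210) or mock replicate 2 (0.0663).

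In the unfolded protein and stress response list 2 of 36 fell, 0 rose and 34 did not pass, and 2 fell and 1 rose when adjusted over the list alone. The members that fell were MT1E and ASNS, the asparagine synthetase, from 1702 ± 772 to 559 ± 81.7 (log2 difference -1.50). MT1E is a metal-binding protein and ASNS an amino acid enzyme, and neither is a chaperone. The list was called lower (camera adjusted p = 0.0205, but adjusted p = 0.418 with an estimated correlation). It kept its call in 13 of 20 other settings. It was not called among the arrays with the suffix (adjusted p = 0.496) or without clone 5B3 (0.163) or 6D2 (0.125). Nor was it called without beta4 replicate 1 (0.0588), beta4 replicate 2 (0.0755) or mock replicate 1 (0.210).

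Lysophospholipid synthesis and receptor genes were called higher as a list (camera adjusted p = 0.0205, and adjusted p = 0.00656 with an estimated correlation). The estimate was -0.005, below the preset, so the second test is the more lenient one. Of 16 members 2 rose, 1 fell and 13 did not pass, with the same 2 and 1 when adjusted over the list alone. Besides ENPP2, AGPAT5, an acyltransferase, rose from 1087 ± 460 to 2279 ± 463 (log2 difference 1.13). LPCAT1, which turns lysophosphatidylcholine into phosphatidylcholine, fell from 1157 ± 267 to 611 ± 23.0 (-0.88), a call lost in 14 of 26 other settings. ENPP2 is on this list as a gene known from the study, and its large rise enters the list test. The list was not tested without ENPP2, so the call does not show that the other members rose as a group. The list kept its call in 16 of 20 other settings. It lost it among the arrays with the suffix (adjusted p = 0.131) and without clone 5B3 (0.211), beta4 replicate 2 (0.0567) or mock replicate 1 (0.0553).

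Among cadherins, tight junction genes and regulators of epithelial-mesenchymal transition 2 of 19 rose, 0 fell and 17 did not pass, and 3 rose and 1 fell when adjusted over the list alone. The desmosomal cadherin DSG2 rose from 59.1 ± 39.8 to 428 ± 70.9 (log2 difference 2.71) and CDH19 from 140.0 ± 43.6 to 533 ± 190.1 (1.78). The list was called higher (camera adjusted p = 0.0427, but adjusted p = 0.0654 with an estimated correlation). It kept its call in 10 of 20 other settings. It was not called on the mean statistic over a gene's probe sets (adjusted p = 0.0967), with no filter (0.198), among the arrays without the suffix (0.106) or without clone 5B3 (0.247) or 6D2 (0.237). Nor was it called without beta4 replicate 2 (0.0926), beta4 replicate 4 (0.084), mock replicate 1 (0.0811) or mock replicate 3 (0.189).

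The NFAT and calcineurin list was called higher (camera adjusted p = 0.0427, and adjusted p = 0.00153 with an estimated correlation). The estimated correlation was negative (-0.059), which makes the second test more lenient than the first. Of its 10 members 1 rose, 0 fell and 9 did not pass, as also when adjusted over the list alone. SLC5A3, a myo-inositol transporter, rose from 1139 ± 133 to 3193 ± 558 (log2 difference 1.47). This list kept its call in 4 of 20 other settings. It lost it without beta4 replicate 1, 2 or 3 and without mock replicate 1, 2 or 3 (adjusted p between 0.0865 and 0.213), and the highest adjusted p over the 20 settings was 0.341. Fibroblast and stromal markers were called higher too (camera adjusted p = 0.0427, and adjusted p = 6.38e-06 with an estimated correlation). Here too the estimated correlation was negative (-0.094) and the second test more lenient. Of 9 members 1 rose, S100A4, which is known from the study, and 1 fell, the matrix protein MGP from 4185 ± 838 to 2432 ± 355 (-0.77). The MGP call was lost in 14 of 26 other settings. The markers were not tested without S100A4, so the call does not show that the others rose as a group. The other 7 did not pass, with the same counts when adjusted over the list alone. Their call held in 8 of 20 other settings and was lost without beta4 replicate 1 or 2 and without mock replicate 1, 3 or 4 (adjusted p between 0.0567 and 0.0991), and the highest adjusted p over the 20 settings was 0.273.

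In the actin cytoskeleton and motility list 5 of 55 rose, 3 fell and 47 did not pass, and 8 rose and 3 fell when adjusted over the list alone. MARCKS, CAPG and PDLIM4 are named above, and the actin-membrane linker EZR rose from 320 ± 8.0 to 561 ± 97.4 (log2 difference 0.77). MYL9, a regulatory light chain of myosin, fell from 2072 ± 433 to 415 ± 107 (-2.29) and MYLK, the kinase of such chains, from 773 ± 480.3 to 376 ± 242 (-0.98). The list as a whole was not called (camera adjusted p = 0.914). Among other called genes, which the naming rule picked from the results, ARHGEF3 rose from 208 ± 66.1 to 795 ± 323 (1.82). RAC2 fell from 2258 ± 311 to 709 ± 454 (-1.83), ARHGAP29 from 330.1 ± 59.9 to 156 ± 42.5 (-1.02) and CDC42EP1 from 1136 ± 255 to 221 ± 188 (-2.61).

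Of 31 matrix proteases and inhibitors 3 rose, 1 fell and 27 did not pass, and 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.499). ADAMTS1, a secreted metalloprotease, rose from 20.7 ± 16.7 to 240.4 ± 73.2 (log2 difference 2.86). MMP14, a membrane-bound matrix metalloprotease, rose from 958 ± 71.5 to 1615 ± 156 (0.74) and the cathepsin CTSB from 1500 ± 213 to 2549 ± 260.3 (0.77). CTSL fell from 299.7 ± 63.3 to 169 ± 49.2 (-0.79), a call lost in 16 of 25 other settings. Of 27 fibrillar and interstitial matrix genes 2 rose, 3 fell and 22 did not pass, and 3 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.914). COL5A2 rose from 475 ± 150 to 1068 ± 236 (1.16) and tenascin C (TNC) fell from 6642 ± 294 to 2743 ± 654 (-1.30). In the hemidesmosome and laminin list HSPG2, the basement membrane protein perlecan, rose from 230 ± 139 to 519 ± 210.1 (1.19). In it 0 of 9 fell and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.299). Of 15 integrin subunits 0 passed the test, also when adjusted over the list alone (camera adjusted p = 0.994). ITGA2 gave 335 ± 57.5 against 213 ± 63.5 (0.64, limma adjusted p = 0.111). ITGA10 gave 424 ± 109 against 251 ± 46.7 (0.70, limma adjusted p = 0.125). In the S100 family S100A4 rose, S100A2 fell from 527 ± 58.8 to 282 ± 95.7 (-0.92) and 9 of 11 did not pass. The counts were 1 that rose and 2 that fell when adjusted over the list alone (camera adjusted p = 0.914).

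In TGF beta and BMP signalling 4 of 37 rose, 1 fell and 32 did not pass, and 5 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.914). FST, the activin antagonist follistatin, rose from 669 ± 43.7 to 4822 ± 1888 (log2 difference 2.75) and the matricellular protein CCN2 from 165 ± 55.0 to 484 ± 131 (1.49). TGFBI, a matrix protein induced by TGF beta, fell from 4629 ± 672 to 1739 ± 266 (-1.41). In Wnt signalling SFRP1 and the receptor FZD7 rose, DKK1, a secreted Wnt antagonist, fell from 501 ± 139 to 149 ± 72.5 (-1.70) and 17 of 20 did not pass. The counts were 2 and 1 when adjusted over the list alone (camera adjusted p = 0.914). The FZD7 call was lost in 15 of 26 other settings. Among the EGF family and other growth factor receptors 1 of 32 rose, 3 fell and 28 did not pass, and 2 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.183, but called lower without clone 6D7, adjusted p = 0.0392). The binding protein IGFBP7 fell from 3692 ± 701 to 820.3 ± 166 (-2.15), FGF13 from 579 ± 264 to 149 ± 39.5 (-1.78) and EFNA1 by 1.10 on the log2 scale. The receptor EPHA3 rose from 488 ± 255 to 1224 ± 620 (1.28). Of 18 metastasis suppressors 2 rose, MAP2K6 from 176 ± 71.9 to 596 ± 32.3 (1.75) and CCN2, 0 fell and 16 did not pass, also when adjusted over the list alone. The test gave no call (camera adjusted p = 0.299, but adjusted p = 5.23e-05 with an estimated correlation). That estimate was negative (-0.052), which makes the second test more lenient than the first.

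Of 58 cell cycle genes 2 rose, 2 fell and 54 did not pass, and 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.914). MYBL2 rose from 1132 ± 352 to 2782 ± 1206 (log2 difference 1.23), and the cyclins gave a rise of CCNE1 (0.67) and falls of CCND1 (-1.36) and CCNB2 (-0.63). These cyclin calls were lost in 18, 16 and 17 of 26 other settings, and the groups overlapped in CCNE1 and CCND1. Of the other called list members named in the text, HSPG2, MYLK, EPHA3, IL24 and ENO2 had overlapping groups as well. Of 36 hypoxia and glycolysis genes 2 rose, 1 fell and 33 did not pass, also when adjusted over the list alone (camera adjusted p = 0.914), with SLC2A3 lower, ENO2 higher (1.31) and P4HA2 higher (0.86). The P4HA2 call was lost in 16 of 26 other settings. Of 24 cholesterol and fatty acid synthesis genes (camera adjusted p = 0.391) and 26 cyclic AMP signalling genes (camera adjusted p = 0.914) 0 passed the test, also when adjusted over each list alone. The smallest p belonged to DHCR7 (-0.67, limma adjusted p = 0.102), and SC5D (-0.61, limma adjusted p = 0.135), and to the phosphodiesterase PDE2A (-2.10, limma adjusted p = 0.0633) and RAPGEF2 (0.67, limma adjusted p = 0.0873). Of 24 melanocyte lineage genes TYRP1 rose, RAB27A fell from 2929 ± 713 to 1297 ± 464 (-1.20) and 22 did not pass. The counts were 3 that rose and 2 that fell when adjusted over the list alone (camera adjusted p = 0.499). The list was called higher in beta4 without clone 3A7 (median 0.47, adjusted p = 0.000178) and had a median of -0.13 without clone 5B3 (adjusted p = 0.0608). Of 11 epithelial and mammary markers 0 rose, KRT18 fell from 3823 ± 548 to 1874 ± 722 (-1.10) and 10 did not pass. The counts were 1 that rose and 2 that fell when adjusted over the list alone (camera adjusted p = 0.558, but called lower with no filter, adjusted p = 0.0454). The S100, matrix protease, fibrillar matrix, actin, TGF beta and cell cycle lists had a median below 0 and a test direction above it. The hypoxia list had the reverse, and in the cyclic AMP list the mean lay below 0 with median and test above.

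**Figure D3:**
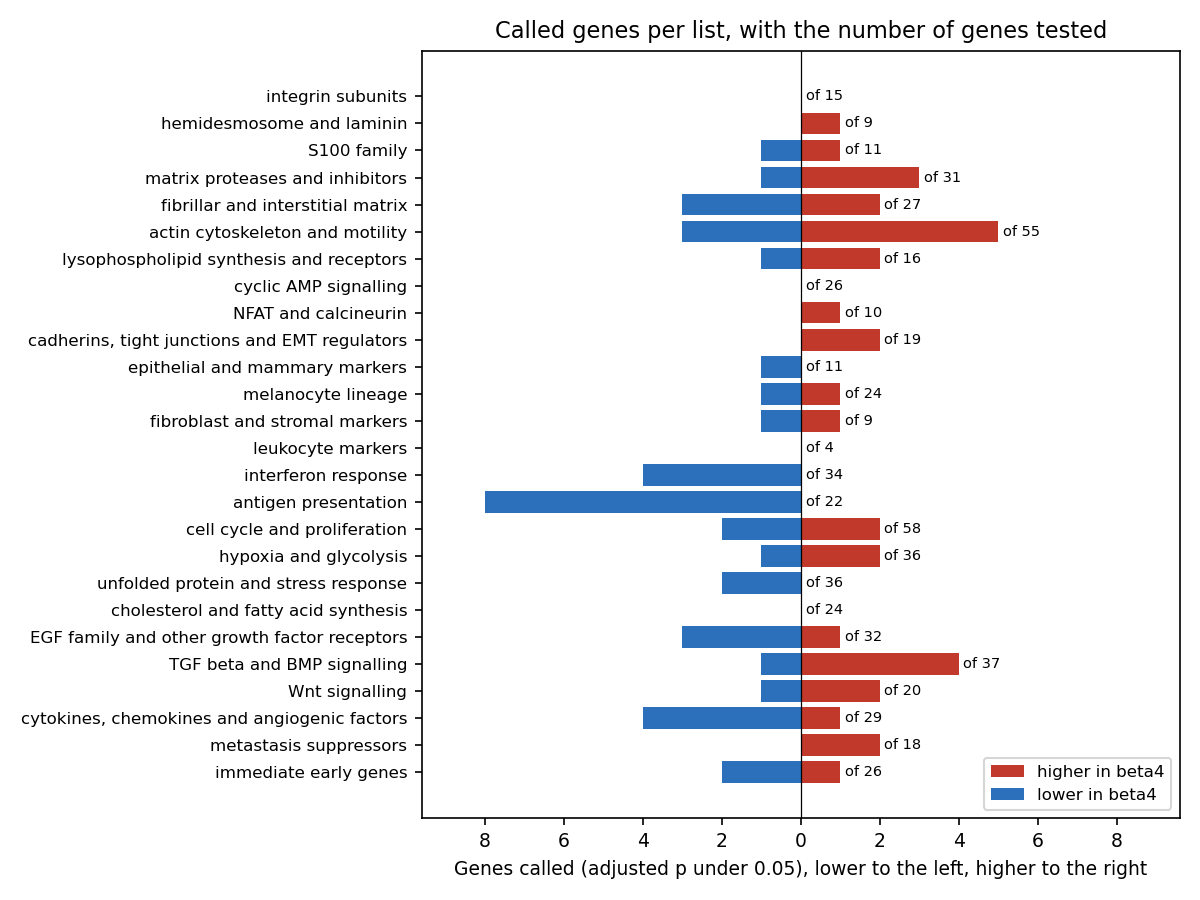
Number of genes called per list between beta4 and mock, higher in beta4 to the right and lower to the left, with the number of tested genes of each list beside its bar. Antigen presentation has the longest bar, with 8 of 22 genes lower and 0 higher.

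Genes that lie next to each other on a chromosome differed in the same direction between beta4 and mock. Over 7962 tested genes in the order of the reference annotation (GRCh38.p14), the differences of genes 10 places apart correlated with a rank correlation of 0.153. This stands against at most 0.031 in 1000 shuffled orders (permutation p = 0.001, the smallest these shuffles can give). Genes are not independent replicates in such a correlation. The median difference of the 20 neighbours on each side passed the highest value of shuffled orders for 430 genes (5.4%). Among them were a stretch of 70 genes from ID1 to TTPAL with a median of 0.45 and a stretch of 54 genes from PPFIA1 to RAB38 with a median of -0.46. Such stretches held 23.3% of the called genes and 4.5% of the others. Genes of a stretch share neighbours, so these shares come without a test. Of the 24 genes with the largest rises and falls, 14 (58.3%) had neighbours with a median in their own direction. That share was 78.6% of all called genes (86.2% of those that differed by less than 2-fold and 71.2% of the rest) and 63% of the genes not called. Of the 24, 5 lay past the highest shuffled value (0.378). The neighbours of NNMT (median -0.40), SERPINA3 (-0.43) and UCP2 (-0.44) had the gene's direction, and those of MT1E (0.46) and TMPRSS15 (0.385) the opposite one. Among the other called genes named above, CTSB (0.40), AGPAT5 (0.41) and MYBL2 (0.44) had neighbours past that value in their own direction and MYL9 (0.59) in the opposite one. PDE2A (-0.45), DHCR7 (-0.43) and SC5D (-0.43), which were not called, had neighbours past it with the sign of their own difference.

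**Figure D4:**
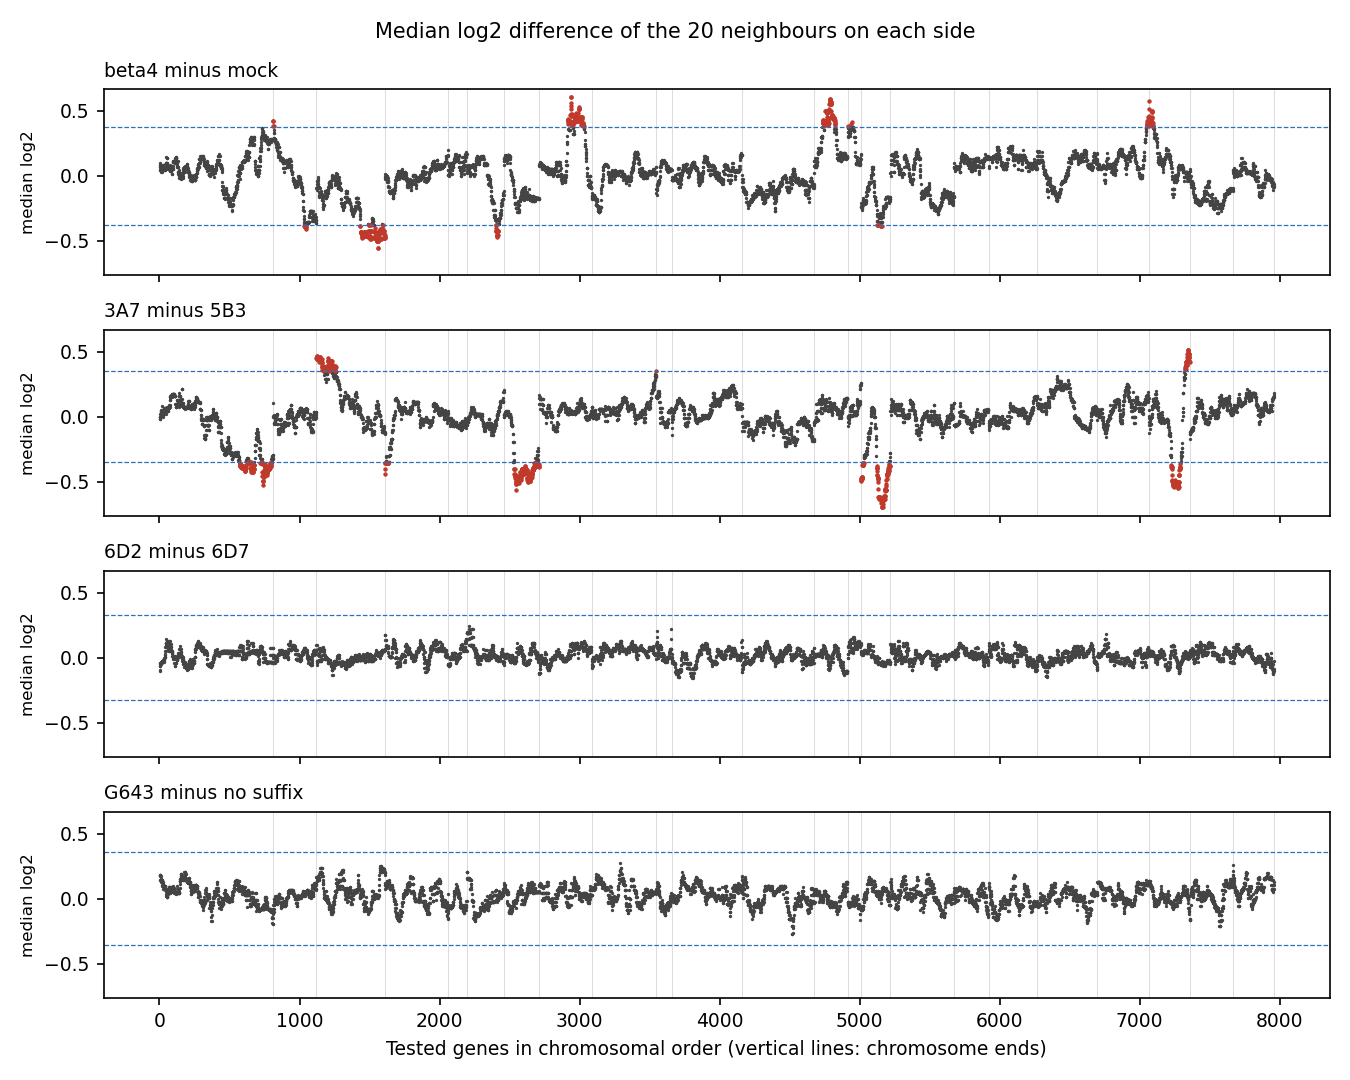
Median log2 difference of the 20 tested neighbours on each side of a gene, for tested genes in chromosomal order (7962 genes), in the 4 comparisons. Dashed lines mark the highest value of shuffled orders and red points the genes past it, 430 for beta4 minus mock, 654 for 3A7 minus 5B3 and 0 in the other panels.

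The beta4 clones were compared to see how far 2 clones of the same transfection differ. The pigment cell genes GPR143 and TYRP1 were much lower in 3A7 than in 5B3. GPR143, a receptor of melanosomes, had a mean signal of 6.4 in 3A7 and 1029 in 5B3 (2 arrays each; log2 difference -5.52, SE 0.24, limma adjusted p = 0.00061). Its size depends on the offset (-7.10 with an offset of 1 and -3.93 with 64), since the signal in 3A7 lies below 16. TYRP1 had 383 and 2974 (-2.90, limma adjusted p = 0.0143) against 128 and 107 in the mock clones 6D2 and 6D7. HAPLN1, which links proteoglycans to hyaluronan (-4.44), the transcription factor ARNT2 (-3.74), PHACTR1 (-3.46) and the aldehyde dehydrogenase ALDH1A1 (-3.04) were the other largest differences towards 5B3. Higher in 3A7 were CST7, a cystatin (3.43), the guidance factor SLIT2 (2.53), IGFBP6 (2.40), RAC2 on its dimmer probe set (2.38) and the reductase AKR1C1 (2.25). In all, 57 probe sets were called, 23 higher and 34 lower in 3A7, with 1687 at an unadjusted p under 0.05. Of these 57, 3 were also called between beta4 and mock, TYRP1, CRYAB (mean signal 1054 in 3A7, 5774 in 5B3, 205 in 6D2 and 171 in 6D7) and COL13A1 (350.2, 81.4, 833 and 1220.2). They were chosen for mention after their values were seen. The count was 2 with no filter, 13 with an offset of 1 and 235 with an intensity trend, and each clone has 2 arrays, 1 per suffix.

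Between the mock clones 6D2 and 6D7 limma called 0 of 13329 probe sets, with 722 at an unadjusted p under 0.05, and 0 under each of the other settings run. The median absolute log2 difference was 0.18, against 0.22 between the beta4 clones and 0.23 between beta4 and mock. The clone values rest on 2 arrays per side and the group value on 4. Noise between arrays thus adds more to the clone values, and the group value cannot be compared with them directly. In simulated data with the same layout this comparison recovered 14% of probe sets changed by 1 and 70.2% of those changed by 2 on the log2 scale.

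The comparison of arrays with and without the suffix G643 shows how far the 2 sets of arrays differ. PRKG2, a cyclic GMP-dependent kinase, had a mean signal of 34.7 without the suffix and 199.7 with it (log2 difference 2.08, SE 0.152, limma adjusted p = 0.0163, 4 arrays each). The actin crosslinker ACTN1 had 520.3 and 1975 (1.81), with DEPP1 (1.73), MC2R (1.63) and AHDC1 (1.51) next. EPHA3 had 992 without the suffix and 131 with it on the dimmer of its tested probe sets (-3.03), followed by LMAN1 (-2.63), AZIN1 (-2.45), NFIB (-2.35) and GPR22 (-2.35). Of 743 probe sets called, 229 were higher and 514 lower with the suffix, 302 of them by 2-fold or more, with 3492 at an unadjusted p under 0.05. The count was 1 with no filter. Controls added to the samples differed too, in both directions. The bioB control averaged 698 ± 111 without the suffix and 222 ± 26.3 with it (SD, n = 4 each; exact permutation test, 2-sided p = 0.0286, the smallest that 4 against 4 allows). The controls bioC (1852 and 567) and cre (27661 and 10449) were lower with the suffix as well and lys (1691 and 3688) was higher, with the same p, while phe gave 6216 and 8290 (exact permutation p = 0.0857). The ratio of 3' to 5' signal for GAPDH was 0.773 ± 0.034 and 0.949 ± 0.068 (exact permutation p = 0.0286), and that for ACTB 1.39 ± 0.129 and 1.31 ± 0.124 (exact permutation p = 0.457). Between beta4 and mock the GAPDH ratio was 0.838 ± 0.088 and 0.884 ± 0.131 (exact permutation p = 0.629). These permutation tests exchanged single arrays as if they were independent and ignored the clones. Each clone has 1 array with and 1 without the suffix. Exchanges within clones allow only 8 choices, too few for a share under 0.05. The suffix is present on the same number of arrays in both groups and stands as a term in the comparison of beta4 with mock.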

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

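The tests in this part on other splits and pairings, gene order, neighbouring genes, the HLA region and interferon genes outside the antigen presentation list, and the use of leukocyte markers to weigh that list, were chosen after the results they concern had been seen.

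In 8 of 202 groups of 4 values, 1 array lay far from the other 3 of its group on the log2 scale; chance alone gives about 10.1. For MARCKS, on the probe set with its largest rise, mock replicate 2 had a signal of 71 against 6.5 to 12.1. For COL9A3 mock replicate 1 had 31.4 against 13 to 14.9. For MT1E beta4 replicate 3 had 933.9 against 593.8 to 611.8. For S100A2 mock replicate 3 had 614 against 489.3 to 507.5. For PDE2A beta4 replicate 2 had 9.6 against 109.3 to 143.4, and mock replicate 1 had 507 against 352.3 to 363.2. For EFNA1 mock replicate 3 had 320.6 against 389.7 to 401.9. For FOSL1 mock replicate 1 had 12126.7 against 8703.8 to 9188.7.

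Among the probe sets under the signal filter, which the comparison of beta4 with mock leaves out, a fit without the filter called 26, of which 16 were higher and 10 lower in beta4. Among those higher were the actin-bundling protein FSCN1 (mean signal 164 in beta4 and 6.3 in mock) and the transcription factor SOX4 (206 and 12.2), and among those lower the keratin KRT7 (8.2 and 158). No size is given for them, because without detection calls it is not known whether the lower signals lie above background.

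The first pattern is the number of probe sets called between beta4 and mock. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least 554 calls, the real one and the split along the suffix with 1239 (fitted without the suffix term, with which it coincides). The sets of arrays are thus a strong structure of these data, and chance cannot be excluded from this count. With the suffix split left out, 1 of 34 splits, the real one, gave as many, and the highest other gave 1; within the suffix sets the counts were 91 and 43. For the lists, 1 of 35 splits, the real one, called as many as 9, and the highest other 6, which argues against chance if single arrays could be exchanged. They come in clones and suffix sets, however. Of the 18 splits that hold the suffix equally on both sides 1, the real one, called 9 and the highest other 6, and of the 3 ways to pair the clones 1, the real one, called 9 on clone means and the highest other 3. Both are too few for a share under 0.05. Copy number differences of long chromosome stretches alone are argued against by 338 of the 554 calls that stayed once neighbour medians were subtracted. A gain or loss of a single gene or a short stretch barely moves these medians, so the subtraction cannot test it. Nothing was subtracted from the 52 of the 554 calls that lack a single gene symbol, so the 338 can include some of these. The 3 ways to pair the 4 clones, of which 1 gave 125 calls on clone means and the highest other 0, are too few for a share under 0.05, so an effect of beta4 and other differences between these clones cannot be told apart.

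The suffix comparison has 8 choices of the suffixed array per clone, too few for a share under 0.05; 1 gave 743 calls, the real one, and the highest other 0.

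The second pattern is that neighbouring genes differ in the same direction between beta4 and mock. Tandem families that share probes are argued against by a rank correlation that was still 0.153 between genes 10 places apart. A difference between the sets of arrays is argued against by 0.006 at that distance in the suffix comparison, which lies within shuffled orders. A candidate explanation is that the clones differ in the copy number of chromosome stretches: the correlation was 0.155 between genes 20 apart (highest shuffled order 0.038), and 0.146 between the beta4 clones at 10 apart, while the mock clones gave 0.011. Copy number itself was not analysed here, and whether beta4 has any part in the pattern was not tested.

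The third pattern is the lower signal of antigen presentation genes in beta4. Leukocytes in the mock cultures stay open. Their 17 markers were not called as a set with no filter (median -0.094, camera adjusted p = 0.87), but only 4 of them lay above the signal filter, and signals near background set no bound on a share of such cells. A lower copy number of the HLA region is argued against by the 47 other tested genes between HLA-F and HLA-DPB1, whose median difference was -0.081 (quartiles -0.274 and 0.136), where the 17 antigen presentation genes there had -0.88 (-1.12 and -0.69). Lower interferon-type signalling may contribute, as a hypothesis, since 31 interferon response genes outside the antigen presentation list had a median of -0.223 (p = 0.0141 with an estimated correlation). Whether beta4 itself or another difference between the clones lies behind it stays open.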

How the results depend on the processing

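Tests without both suffix and block, with neighbour medians subtracted and of lists within suffix sets were chosen after the results were seen. The labels give no replicate numbers that pair single arrays across groups. The suffix, which both groups share, is a term of the fit: deviations from the group means correlated by 0.199 to 0.385 between arrays of the same suffix in different groups and by -0.319 to -0.2 between others. The count of 554 between beta4 and mock stayed within 1.5 times under both offsets (479 and 776), quantile (589) and median scaling (592), the 60th percentile filter (779), no block (801), no suffix term (783), neither (405) and neighbour medians subtracted (413). It was 291 with a log2 difference of at least 1 required, 200 with no filter, 972 with a trend, 125 on clone means (114 of them among the 554), 91 and 43 without and with the suffix, 169 to 617 without 1 array, and 1314, 979, 96 and 98 without 3A7, 5B3, 6D2 and 6D7. Fewer arrays leave fewer degrees of freedom and a required size can only lower a count; for the other settings and for higher counts the cause was not tested. The 57 calls between the beta4 clones became 13 (offset 1), 134 (offset 64), 2 (no filter), 162 (60th percentile), 235 (trend) and 113 (beta4 arrays only). The suffix count of 743 became 302 (log2 difference of at least 1), 1205 (offset 64), 1 (no filter), 1137 (60th percentile) and 1457 (trend). For both, the cause was not tested. The mock clones gave 0 throughout. The 9 lists became 3 among suffixed arrays, 4 without 5B3, 3 without 6D2 and 3 to 8 without 1 array (3 without mock replicate 1, 4 without beta4 replicate 2, 5 without beta4 replicate 1). Of 89 named probe sets, 79 were called, and the 79 kept their direction in every setting run, 20 of them their call too; of 2276 values 1750 kept side and direction, 508 fell short of the threshold, 14 passed it newly and 4 reversed. Those were ITGA6 on its brighter probe set, -0.298 among suffixed arrays, and LAPTM5, which was 0.159 without 5B3, 0.062 without 6D2 and -0.348 to 0.002 without 1 array (0.002 without beta4 replicate 2); neither was called, and the cause was not tested. Signal over background was not measurable without detection calls.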

Other observations

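The values and tests in this part were chosen after the results were seen.

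Melanocyte lineage genes were lower in clone 3A7 than in clone 5B3 as a group. Of 24 tested members 4 were called lower in 3A7 and 0 higher, with a median log2 difference of -0.57 (camera adjusted p = 3.83e-15, and adjusted p = 0.000236 with an estimated correlation). Tyrosinase (TYR), the first enzyme of melanin synthesis, had a mean signal of 270.1 in 3A7, 1626 in 5B3, 584 in 6D2 and 445 in 6D7, and MLANA, a melanosome protein, had 149.9, 744, 290 and 238. MITF, the transcription factor of the lineage, had 1637, 2978, 1431 and 1481. The antigen presentation list was higher in 3A7 than in 5B3, with a median of 0.39 (camera adjusted p = 0.00013, but adjusted p = 0.371 with an estimated correlation), and so were immediate early genes, with 0.33 (adjusted p = 0.0239, but adjusted p = 0.605 with an estimated correlation). Between the mock clones 0 lists were called.

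Between arrays with and without the suffix 3 lists were called. Cadherins and related genes were lower with the suffix, with a median of -0.40 (camera adjusted p = 0.0084, and adjusted p = 7.6e-06 with an estimated correlation). That estimate was negative (-0.023), which makes the second test more lenient than the first. Actin cytoskeleton genes were higher (adjusted p = 0.0166, but adjusted p = 0.181 with an estimated correlation), as were cell cycle genes (adjusted p = 0.0232, but adjusted p = 0.0512 with an estimated correlation).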
